A study of Gallus gallus with 6 samples.

How the data were processed

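The study measured gene expression by RNA-seq in 6 libraries from chick (Gallus gallus) cochlear duct explants, 3 SM controls and 3 SM plus BQ788, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, ducts of chicks at post-hatch day 1 were cultured in DMEM with 1% serum at 37 °C and 5% CO2, treated with streptomycin for 48 h and then with or without BQ788. The sensory epithelium was lifted off with thermolysin at 500 µg/ml, so neighbouring cells could be carried over, and 400 ng of total RNA entered NEBNext Ultra II library preparation. The dose and times of BQ788 are not given in the sources used here, nor is the number of explants per library or a selection of poly(A) RNA.

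The values deposited by the authors are FPKM per gene, fragments or reads scaled to gene length and library size, in 1 table with gene coordinates, lengths, biotypes and descriptions. Per the submitters' processing notes fastp was used and the genome build was GRCg7b; the aligner and the counter are not given in the sources used here. Of the gene identifiers 25616 matched the annotation table used for chromosome names and 3 did not. Chromosomes and coordinates are those of the table, on GRCg7b.

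Multiplied by gene length, every FPKM value was a whole multiple of 1 step per library within a tolerance of 0.01 of a read (largest distance 3.06e-05), so reads per gene could be recovered. They summed to 17375656, 15438305 and 16180732 in the SM controls and 16728070, 17070306 and 16369723 with BQ788. The totals implied by the FPKM scale were 0.948 to 1.06 times these sums, so the authors divided by a rescaled library size. The median gene at an FPKM of 1 to 1.5 had 69 to 81 reads per library, a counting error of 11.1% to 12.0%. A floor of 3 reads corresponds to 0.169 to 0.193 FPKM in a gene of 1 kb. Both figures cover counting error only, since the reads carried no molecular identifiers. Recovered reads of libraries within a group differed by more than counting noise, with chi-square per degree of freedom from 6.37 to 59.7, which does not tell separate samples from separate preparations of 1 sample. The 6 libraries were treated as separate samples, as titled.

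The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a linear model of group, eBayes with a trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. It covered genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on the log2(FPKM + 1) scale, SM plus BQ788 minus SM control, and understate the change of low genes. For the endothelin axis an exact two-sided permutation test was added, whose smallest possible p with 3 against 3 is 0.1. Data were also simulated with the real genes' means and with spreads moved toward their median, each gene drawn independently. On these the test called 42.6% of genes changed 1.5-fold, 88.8% of those changed 2-fold and 99.2% of those changed 4-fold among 11857 genes. Of its calls 5.28% were false. Shifts shared by many genes within a library were absent, so these shares may not hold for the real data.

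Before the data were examined, 28 gene lists were written for hair cells, supporting cells, signalling pathways, stress, RNA quality and other cell types. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. Beside it stand the number of members past 0.05 over all genes and the number adjusted over the list alone. The lists overlap, and many of their genes are also expressed in other cells of the epithelium. A rule written at the same time chose the genes named. It took the endothelin axis, the 10 largest increases and 10 largest decreases past the threshold with a symbol and with groups that do not overlap, ATOH1, POU4F3, MYO7A, SOX2 and MKI67, and up to 4 members per list with the smallest p. DCN, LUM, COL1A2, MBD2, the genes named by protein domain and the cartilage markers were chosen after their values were seen. Some genes that the rule chose are not reported here.

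Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling and quantile normalization. They also included the replicate number as a block, eBayes without trend or robust, leaving out chromosomes W and Z, limma voom on the recovered reads, fry for the lists, and leaving out each library in turn. Scaling by plain totals of recovered reads and removal of a gene length trend within each library (lowess, span 0.3) were added after the data were seen. Protein domains came from the descriptions in the deposited table. Enrichment of called genes was tested with a one-sided hypergeometric test for domains with at least 10 tested genes. The 95% intervals of list means and of their differences came from the mean over genes in each library and its spread between the libraries of a group, with a pooled variance. For the difference between channel and bundle genes a further interval came from 10000 resamplings of the members of both lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.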

Results

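The data were 6 bulk RNA-seq libraries of chick auditory sensory epithelium, the basilar papilla, kept as explants of the cochlear duct. The ducts came from chicks at post-hatch day 1 and were exposed for 48 h to streptomycin (SM), an aminoglycoside antibiotic that kills hair cells. In birds the surviving supporting cells then replace the lost hair cells. Of the explants labelled day 3, 3 libraries were SM controls and 3 came from explants that also received BQ788, a small molecule that blocks the endothelin receptor type B. The gene table held 25619 rows with FPKM values, of which 5107 were at 0 in every library. Reads recovered from these values came to between 15438305 and 17375656 per library. The labels do not say that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples.

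The comparison of BQ788 with SM alone asked how transcription differed with BQ788 after exposure to streptomycin. No library came from explants without SM, so hair cell replacement, or a link of changes with BQ788 to it, was not measured. The largest decreases included the matrix genes POSTN, COL9A3 and MGP and the peptide genes ADCYAP1 and CCK, and the largest increases the channel genes AQP3 and KCNE4. POSTN, which encodes the matrix protein periostin, fell from 31.8 ± 1.64 to 6.18 ± 0.651 FPKM (mean ± SD, n = 3 per group, here and below), a log2 fold change of -2.19 (SE 0.09, limma adjusted p = 0.000886). COL9A3, a chain of collagen IX, fell from 89.3 ± 11.5 to 30.1 ± 4.17 FPKM. AQP3, a water and glycerol channel, rose from 18.3 ± 3.03 to 45.2 ± 11.3 FPKM, and KCNE4, a potassium channel subunit, from 3.63 ± 0.932 to 9.26 ± 1.29 FPKM.

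Of 11857 genes tested, 355 passed an adjusted p of 0.05, with 89 higher and 266 lower with BQ788. The groups did not overlap in any of the 355, and they did not overlap in 3475 of all genes tested (29.3%, where chance gives 10% on average over splits). With shifts shared by many genes, 1 split can depart far from 10%, so this share alone does not show an effect of BQ788. Most changes were small, since 3 of the higher and 35 of the lower genes reached 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. The median log2 fold change over all genes tested was 0.02. POSTN was the only gene past the threshold when any 1 SM control library, or BQ788 replicate 2, was left out. Without BQ788 replicate 3 the count was 21 genes, and without BQ788 replicate 1 it was 1311.

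Below POSTN and COL9A3, the largest decreases were in SLC45A2, a melanosomal transporter (-1.46), and in SPARCL1, a secreted relative of SPARC (-1.45). ADCYAP1, which encodes the neuropeptide PACAP, fell by 1.43 and MGP, a matrix inhibitor of mineralisation, fell by 1.41 on the log2 scale. CCK, the cholecystokinin gene, went from 5.88 ± 0.127 to 1.85 ± 0.507 FPKM. TSPAN1 (-1.27) and C1QL4 (-1.24) completed the group together with a gene named SMAD4 on chromosome 25 (-1.28). The table holds other rows described as SMAD4, including one on chromosome W, so the assignment of reads among these copies is uncertain. Among genes with a symbol, AQP3 (1.24) and KCNE4 (1.16) rose most, followed by SOUL, a haem-binding protein gene (1.15), and OSGIN1, an oxidative stress response gene (0.84). GNMT, glycine N-methyltransferase, rose by 0.77, the exporter gene ABCC3 by 0.71 and SCNN1B, a subunit of the epithelial sodium channel, by 0.71. SLC46A3, a lysosomal transporter (0.70), and CENPM, a centromere protein gene (0.65), also rose, and the genes named here had adjusted p-values of at most 0.0468. In GRCg7b coordinates from the table, POSTN lies on chromosome 1 from 171879363 to 171912629, COL9A3 on chromosome 20 from 8684111 to 8715865, AQP3 on chromosome Z from 7642457 to 7656705 and SMAD4 on chromosome 25 from 1746329 to 1754554.

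**Figure D1:**
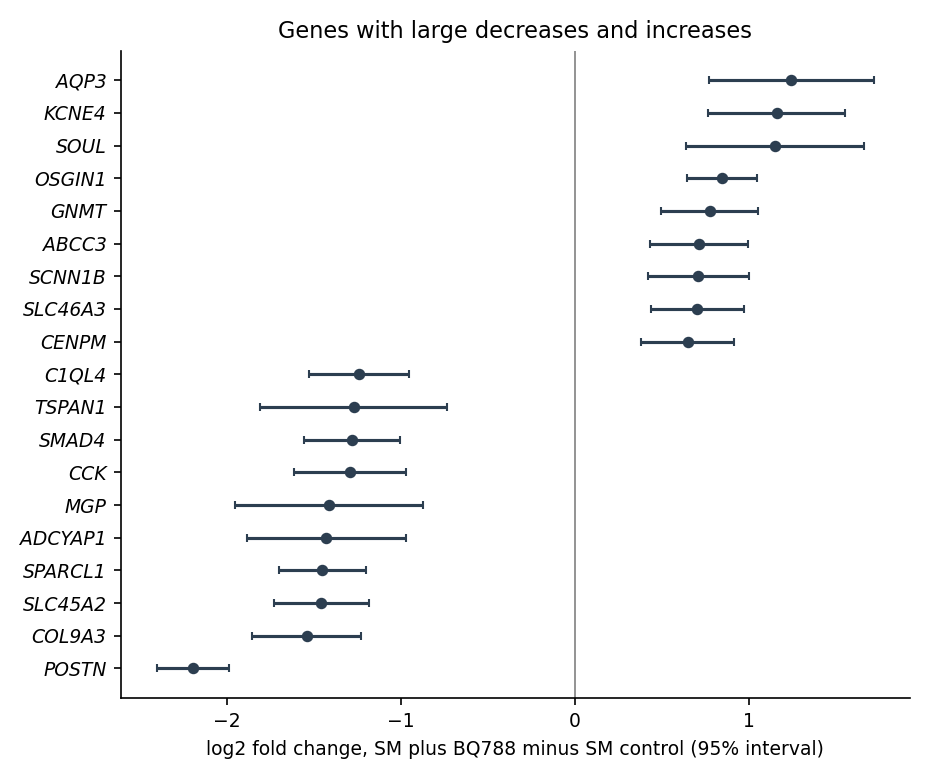
Log2 fold change, SM plus BQ788 minus SM control, of the 10 genes with the largest decreases and of genes with large increases past adjusted p 0.05; points are limma estimates and bars 95% intervals, from 3 libraries per group. POSTN stands lowest at -2.19 and AQP3 highest at 1.24.

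Transcripts of the endothelin axis itself were measured in every library, and none of the 7 genes tested passed the threshold. EDNRB2, the second type B receptor gene of birds (chromosome 4, 11117090 to 11128197), was the most abundant, at 147.6, 164.1 and 127.2 FPKM in the SM controls and 159.9, 127.7 and 101.3 FPKM with BQ788 (log2 fold change -0.19, SE 0.18, limma adjusted p = 0.569). EDNRB (chromosome 1, 153874464 to 153888787) was far lower, at 1.57 ± 0.410 and 2.09 ± 0.517 FPKM. The ligand gene EDN1 was at 13.1 ± 4.56 and 17.7 ± 7.97 FPKM, and EDN2 at 2.39 ± 0.219 and 3.15 ± 0.455 FPKM. EDN2 was the only axis gene whose groups did not overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. EDNRA (0.07), ECE1 (-0.11) and ECE2 (-0.11) moved little, and EDN3, PHEX and KEL stayed below a mean of 1 FPKM and were not tested. At an unadjusted p of 0.05, 1 axis gene passed in limma, and limma voom on recovered reads called 0. BQ788 acts on the receptor protein, so these transcript levels do not check the labels. Nor do they show which of EDNRB and EDNRB2 it blocked. The axis list as a whole did not pass (camera adjusted p = 0.897).

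**Figure D2:**
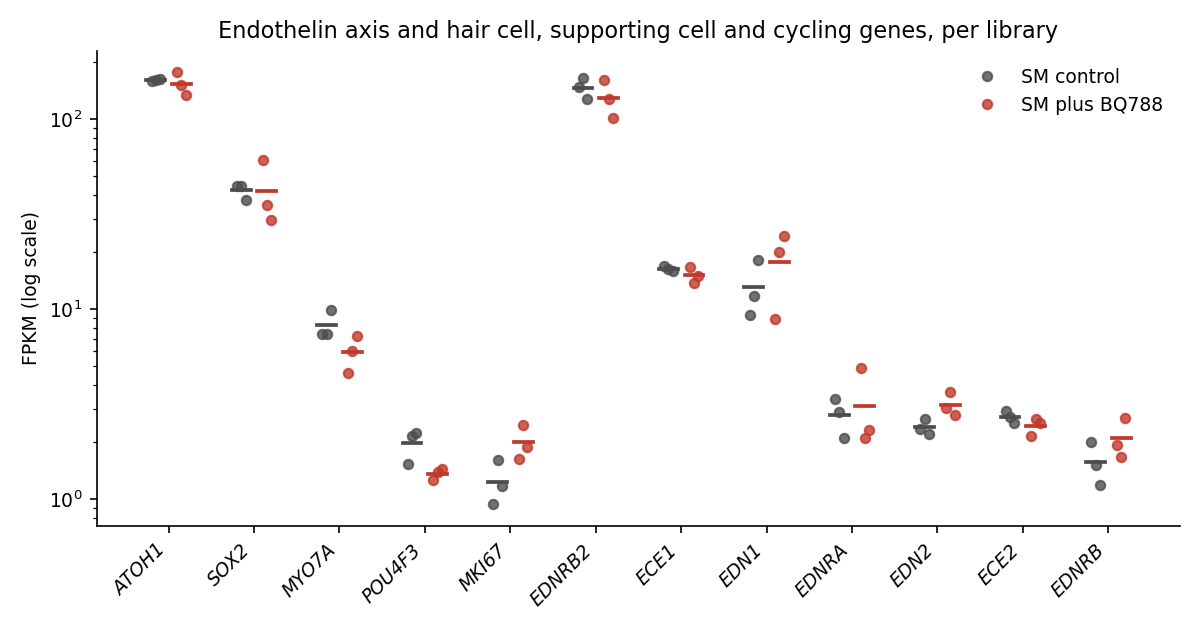
FPKM per library on a log axis for ATOH1, SOX2, MYO7A, POU4F3, MKI67 and the 7 tested endothelin axis genes; points are single libraries (grey SM control, red SM plus BQ788) and short lines the means of 3 libraries. ATOH1 and EDNRB2 lie above 100 FPKM in every library, while EDNRB lies between 1.19 and 2.67 FPKM.

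Among genes of the hair cell lineage, ATOH1, the transcription factor that starts hair cell formation, was at 160.9 ± 2.64 FPKM in the controls and 153.8 ± 21.3 FPKM with BQ788 (limma adjusted p = 0.711). POU4F3, a hair cell survival factor, was at 1.97 ± 0.380 and 1.36 ± 0.0924 FPKM, and MYO7A, a motor protein of the hair bundle, at 8.24 ± 1.44 and 5.98 ± 1.31 FPKM. Both were lower in all 3 BQ788 libraries than in any control, and neither passed (adjusted p = 0.175 and 0.213). NHLH1, a basic helix-loop-helix gene of the hair cell fate list, fell from 12.2 ± 1.72 to 6.63 ± 0.584 FPKM and was the only 1 of 18 tested members past the threshold, over all genes and adjusted over the list alone. BARHL1 (-0.52) and EYA1 (0.20) followed it by p. This list did not pass as a whole (camera adjusted p = 0.124).

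Hair bundle and mechanotransduction genes lay lower with BQ788, with 22 of 29 tested members below 0 and a median log2 fold change of -0.26 (camera adjusted p = 0.000820). The call was lost with adjusted p = 0.646 with an estimated correlation. MYO1H, an unconventional myosin, fell from 14.5 ± 1.38 to 6.82 ± 0.736 FPKM and alone passed over all genes, while 7 members passed adjusted over the list alone. The actin bundling genes ESPN (-0.56, adjusted p = 0.0540) and FSCN2 (-0.75, adjusted p = 0.0590) and LHFPL5, a subunit of the transduction channel complex (-0.47, adjusted p = 0.0802), came closest after it. Of 20 tested genes for hair cell channels, calcium buffers and ribbon synapses, 0 passed in limma, 0 in limma voom and 7 at an unadjusted p of 0.05, all lower (camera adjusted p = 0.146). Those with the smallest p were TMEM255B (-0.51), TMPRSS3 (-0.50), SYT14 (-0.30) and SLC17A8, the vesicular glutamate transporter of hair cells (-0.34).

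Supporting cell genes went both ways. FGFR3, a receptor of supporting cells, fell from 126.8 ± 2.08 to 96.6 ± 7.23 FPKM and was the only 1 of 35 tested members past the threshold, while 3 passed adjusted over the list alone (camera adjusted p = 0.464). SOX2, the prosensory and supporting cell factor, was at 42.2 ± 4.00 and 42.0 ± 16.8 FPKM (adjusted p = 0.899). LFNG, a modifier of Notch receptors, was at 44.5 ± 1.41 and 53.7 ± 0.289 FPKM (adjusted p = 0.0516), TECTA, a tectorial membrane protein gene, at 442.0 ± 68.7 and 286.6 ± 29.2 FPKM (adjusted p = 0.0591), and SOX9 at 57.2 ± 5.33 and 44.6 ± 4.00 FPKM. In the FGF list ETV4, a transcription factor induced by FGF signals, fell from 25.8 ± 1.97 to 18.5 ± 0.900 FPKM beside FGFR3, and CNPY2 (-0.15) and IL17RD (0.33) did not pass. Of its 22 tested members 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.210).

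BMP and TGF-beta genes included ID1 and ID3, targets of BMP signals, which fell from 88.1 ± 3.74 to 57.7 ± 3.96 and from 605.8 ± 12.6 to 404.6 ± 47.9 FPKM. They were the 2 of 31 tested members past the threshold, and 6 passed adjusted over the list alone, all lower. The list lay lower (camera adjusted p = 0.0174), a call lost with adjusted p = 0.646 with an estimated correlation and, without BQ788 replicate 1, at adjusted p = 0.237. TGFB1 (-0.37) and SMAD7 (-0.28) did not pass over all genes. Notch genes gave 0 calls among 30 tested members in limma and limma voom, against 6 at an unadjusted p of 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.694), and DTX3L (-0.55), NCSTN (0.18) and NOTCH2 (0.20) came after LFNG by p. In the Wnt list TCF7L1, a transcriptional repressor, fell from 6.13 ± 0.359 to 4.08 ± 0.370 FPKM, alone among 41 tested members over all genes and adjusted over the list alone, while DKK3 (0.33), DKK2 (-0.43) and FZD6 (0.18) did not pass (camera adjusted p = 0.959). The median of the Wnt list was -0.01 and its mean 0.02, and the median was above 0 under quantile normalization, without chromosomes W and Z, without SM control replicate 3 and without BQ788 replicate 3.

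Proliferation genes lay higher with BQ788, with 55 of 61 tested members above 0 and a median log2 fold change of 0.35 (camera adjusted p = 9.04e-09, but adjusted p = 0.646 with an estimated correlation). MCM4, a subunit of the replicative helicase, rose from 4.10 ± 0.226 to 6.14 ± 0.166 FPKM, and KIF23, a kinesin of cytokinesis, from 1.28 ± 0.120 to 2.26 ± 0.220 FPKM. These 2 passed over all genes and 11 passed adjusted over the list alone, all higher. NUF2 (0.51), ECT2 (0.55) and MKI67, at 1.24 ± 0.337 and 1.99 ± 0.429 FPKM (adjusted p = 0.175), did not pass over all genes. Among members with a mean of at least 5 FPKM the list median was 0.12 (camera adjusted p = 0.0448).

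Genes of the unfolded protein and integrated stress responses lay lower, with 27 of 31 tested members below 0 (camera adjusted p = 0.000168, but adjusted p = 0.646 with an estimated correlation). The folding enzyme genes PDIA4 and PDIA6 fell by 0.46 and dropped by 0.31 on the log2 scale, and MANF, a secreted stress response factor, fell from 114.3 ± 13.5 to 78.0 ± 2.96 FPKM. These 3 passed over all genes and 5 adjusted over the list alone. HSPA5, the chief chaperone of the endoplasmic reticulum, was also lower but did not pass over all genes (-0.53, adjusted p = 0.0727). The cell death list of 31 tested members did not pass as a whole (camera adjusted p = 0.373). Its members RRM2B (0.37) and SESN2 (-0.39) did not pass over all genes. JUND, an AP-1 subunit, fell from 395.4 ± 7.80 to 250.0 ± 31.8 FPKM and was the only 1 of 33 tested immediate early genes past the threshold, ahead of BTG2 (-0.53), IER5 (-0.74) and JUN (-0.43). In that list 2 passed adjusted over the list alone, and it did not pass as a whole (camera adjusted p = 0.0931).

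Interferon and JAK-STAT genes lay lower as a list, with 21 of 26 tested members below 0 (camera adjusted p = 0.00990, but adjusted p = 0.646 with an estimated correlation). No member passed in limma, over all genes or adjusted over the list alone, or in limma voom, and 6 passed at an unadjusted p of 0.05. SOCS1 (-0.93), IRF8 (-0.36), CEBPB (-0.30) and SOCS3 (-0.46) had the smallest p. Without SM control replicate 1 the list's adjusted p was 0.0703, and without BQ788 replicate 1 it was 0.101. Cytosolic ribosomal protein genes shifted by little but in 1 direction, with 54 of 63 below 0 and a median of -0.10 (camera adjusted p = 3.22e-05, but adjusted p = 0.646 with an estimated correlation). Of these 0 passed over all genes, adjusted over the list alone or in limma voom, and 17 passed at an unadjusted p of 0.05, led by RPL14 (-0.26), RPL3 (-0.26), RPL30 (-0.22) and RPS15A (-0.21). The call was lost under quantile normalization (median -0.05, adjusted p = 0.0992) and with the gene length trend removed (median -0.04, adjusted p = 0.128). The share of reads on rRNA genes moved with the same groups, from 1.05% to 1.08% in the controls and from 0.765% to 0.889% with BQ788. Mitochondrially encoded genes made up 1.28% to 2.04% of reads, and 0 of 13 passed in limma, in limma voom or at an unadjusted p of 0.05 (camera adjusted p = 0.243). ND6 (-0.40), ND3 (-0.16), ND1 (-0.18) and ATP8 (-0.18) had the smallest p.

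**Figure D3:**
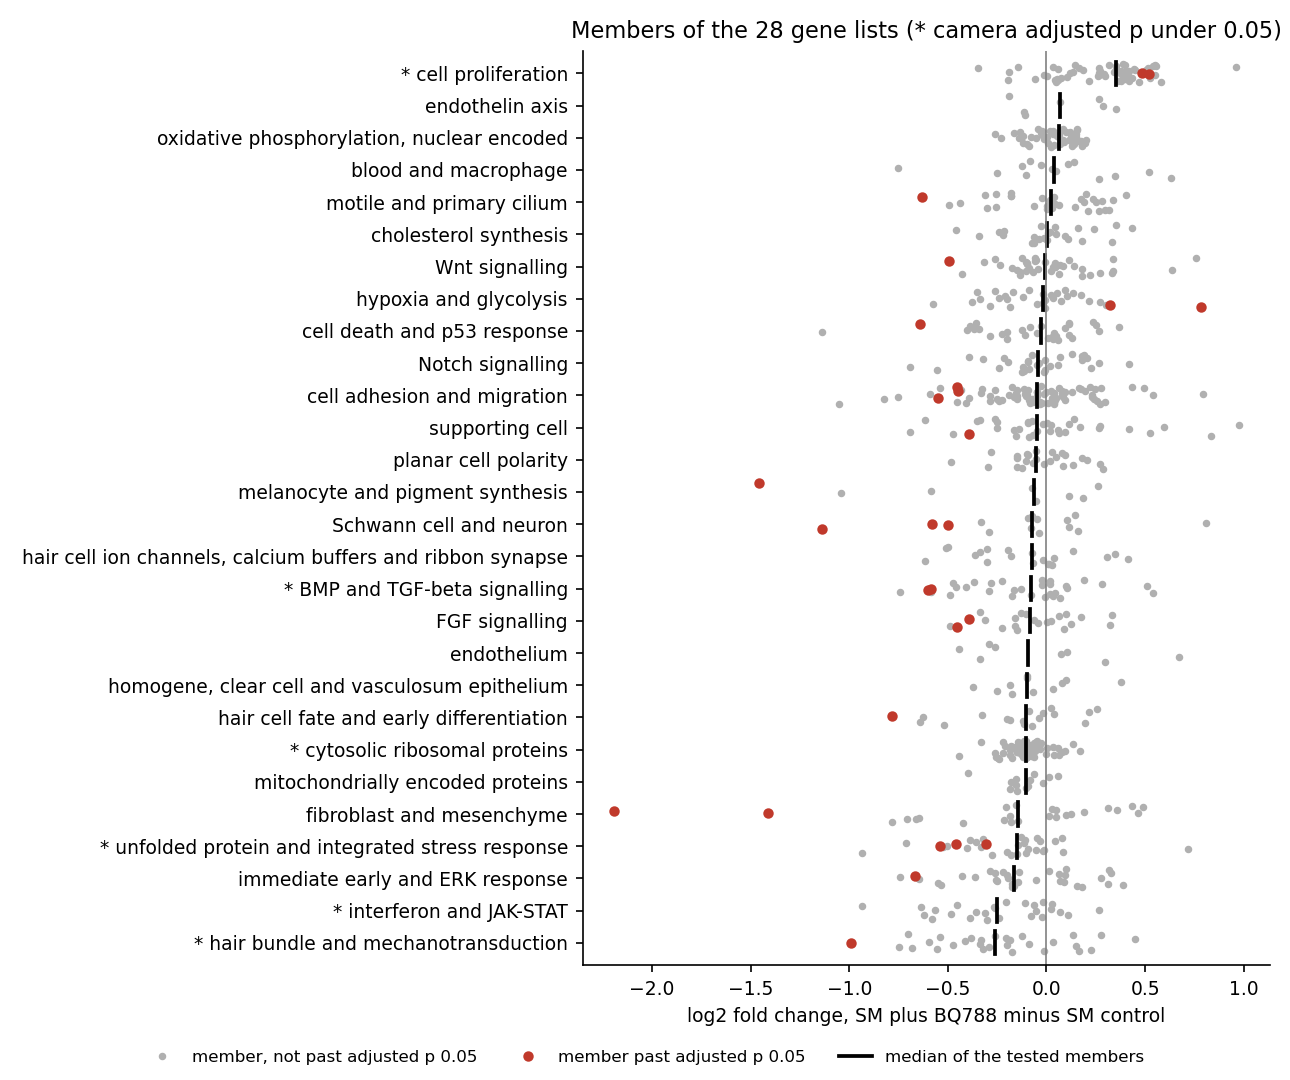
Log2 fold change, SM plus BQ788 minus SM control, of the tested members of 28 gene lists fixed beforehand; red points passed adjusted p 0.05 over all genes, grey points did not, black bars are list medians, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The proliferation list has the highest median, 0.35, and the hair bundle list the lowest, -0.26.

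Adhesion and migration genes included ITGA8, an integrin subunit, which fell from 62.3 ± 4.41 to 42.2 ± 2.64 FPKM. The intermediate filament gene VIM fell from 414.8 ± 23.7 to 301.9 ± 7.42 FPKM and the small GTPase gene RHOB from 140.8 ± 6.06 to 102.9 ± 8.67 FPKM. These 3 of 78 tested members passed over all genes, and 8 passed adjusted over the list alone, 7 of them lower (camera adjusted p = 0.0542). The matrix protease gene MMP7 was at 1.88 ± 0.332 and 3.17 ± 0.0740 FPKM (adjusted p = 0.0525). ROPN1L, a radial spoke gene of motile cilia, fell from 21.8 ± 2.88 to 13.7 ± 1.39 FPKM, alone among 34 tested cilium genes, and 2 passed adjusted over the list alone (camera adjusted p = 0.586). IFT88 (0.34) and BBS2 (0.21) did not pass over all genes. Planar cell polarity genes gave 0 calls among 25 tested in limma and limma voom and 6 at an unadjusted p of 0.05 (camera adjusted p = 0.779), led by CELSR2 (-0.30), FZD6, ANKRD6 (0.29) and VANGL2 (-0.28).

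In the hypoxia and glycolysis list of 31 tested members the mitophagy gene BNIP3 (0.32) rose, while ALDOC (-0.29) and SLC16A3 (-0.35) did not pass (camera adjusted p = 0.799). Nuclear genes of oxidative phosphorylation gave 0 calls among 49 tested in limma and limma voom and 8 at an unadjusted p of 0.05 (camera adjusted p = 0.210), led by NDUFS5 (-0.26), NDUFB4 (-0.23), UQCRC1 (0.16) and UQCRC2 (0.16). Cholesterol synthesis genes likewise gave 0 calls among 24 tested with both tools and 4 at an unadjusted p of 0.05 (camera adjusted p = 0.959), including HSD17B7 (-0.34), PMVK (-0.46) and SC5D (0.24).

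Markers of other cell types that a peeled epithelium can carry moved with the treatment in part. Of 15 tested Schwann cell and neuron genes, GAP43, a growth cone protein gene, fell from 5.53 ± 0.890 to 1.95 ± 0.282 FPKM, and the neurofilament genes NEFM (-0.58) and NEFL (-0.50) also fell. With NTRK2 (-0.33) and 1 more, 5 passed adjusted over the list alone (camera adjusted p = 0.0523). Of 25 tested fibroblast and mesenchyme genes POSTN and MGP fell and 4 passed adjusted over the list alone, including COL6A2 (-0.71) and COL3A1 (-0.79), with a list camera adjusted p of 0.0523. The fibroblast list passed under 5 of 12 alternatives (lowest adjusted p = 0.00291, at a mean of at least 5 FPKM), and its adjusted p ran from 1.77e-05 without BQ788 replicate 1 to 0.528 without BQ788 replicate 2. The Schwann cell and neuron list passed under 5 of 12 as well (lowest adjusted p = 0.0359, with limma voom). The abundant fibroblast transcripts DCN (0.05), LUM (0.12) and COL1A2 (-0.18) did not pass, but these means hide a split among the BQ788 libraries. COL1A2 was at 66.2, 54.6 and 52.1 FPKM in the controls and 84.2, 32.5 and 46.7 FPKM with BQ788. For COL1A2 and COL1A1, BQ788 replicate 1 lay above every control and replicates 2 and 3 below every control. Of 8 tested melanocyte genes SLC45A2 fell and 2 passed adjusted over the list alone, and over all genes MLANA (-1.04, adjusted p = 0.0673), OCA2 (-0.59) and RAB27A (0.26) did not pass (camera adjusted p = 0.246).

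Endothelial markers gave 0 calls over all genes among 8 tested in limma and limma voom, 3 at an unadjusted p of 0.05, and 2 adjusted over the list alone (camera adjusted p = 0.566), from PECAM1 (-0.44), EGFL7 (-0.34), FLT1 (0.67) and RAMP2 (-0.29). Blood and macrophage markers gave 0 of 14 with both tools and 1 at an unadjusted p of 0.05 (camera adjusted p = 0.955), with FCER1G (-0.75), CSF1R (0.52), C1QB (0.63) and C1QC (0.35) at the top. Homogene, clear cell and vasculosum markers gave 0 of 11 with both tools and 1 at an unadjusted p of 0.05 (camera adjusted p = 0.540), with CLDN8 (-0.25), OTX2 (0.38), KCNQ1 (-0.37) and SLC12A2 (-0.10) at the top. The summed level of 8 tested genes on the female-specific chromosome W was 84.6, 81.7 and 77.7 FPKM in the controls and 72.6, 66.9 and 67.5 FPKM with BQ788. MBD2 on this chromosome, named here after its values were seen, fell from 30.3 ± 1.93 to 22.0 ± 1.67 FPKM (adjusted p = 0.0424). Without MBD2 the sums were 56.4, 51.0 and 45.7 FPKM in the controls and 49.2, 46.7 and 45.1 FPKM with BQ788, so the groups overlapped, and the labels do not give the sex of the chicks. On chromosome Z, 17 of 567 tested genes passed, 6 higher and 11 lower, with a median log2 fold change of 0.04.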

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

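Plain totals of recovered reads and removal of the gene length trend were chosen after the data were seen. All 355 genes kept an unadjusted p under 0.05 in limma with each library left out. Their direction could not change there, since the groups did not overlap in any of them. The count of genes changed by BQ788 depended on the setting. It was 68 with no filter on low values (12 higher, 56 lower, more genes tested), 220 with plain totals of recovered reads (47 higher, 173 lower) and 749 with the replicate block (240 higher, 509 lower). With eBayes without trend 59 were higher. Leaving out 1 library gave 1 to 1311 genes, 0 to 626 higher and 1 to 685 lower: 1 without any single SM control or BQ788 replicate 2, 21 without BQ788 replicate 3 and 1311 without BQ788 replicate 1. The replicate numbers were not used as pairs, since not every same-number pair correlated above 0.1 over genes. Pairs 1 and 3 did (0.50 and 0.57). SM control replicate 2 correlated at 0.0744 with BQ788 replicate 2 and at 0.118 with BQ788 replicate 1. SM control replicate 1 correlated at -0.48 with BQ788 replicate 3, and SM control replicate 3 at -0.53 with BQ788 replicate 1. The values correlated were deviations from the group mean, which sum to 0 over the 3 replicates of a group. A low value for pair 2 therefore does not argue against pairing. On each of the first 2 principal components the replicates lay in the order 1, 2, 3 in both groups. An effect shared by replicate number stays possible, and the main model does not remove it. Of the 28 lists, 0 passed with an estimated correlation (adjusted p = 0.646 for each of the 6), 2 with fry directional, Schwann cell and neuron and melanocyte (0.0233 each), not among the 6, and 18 with fry mixed. With fry directional the adjusted p was 0.198 for hair bundle, 0.155 for proliferation, BMP and TGF-beta and ribosomal proteins, 0.266 for interferon and 0.101 for the unfolded protein response; with fry mixed it was 0.0943 for interferon. For ribosomal proteins it was 0.0992 under quantile normalization and 0.128 with the length trend removed. Leaving out 1 library gave 6 to 9 lists and adjusted p from 4.10e-05 to 0.0348 (hair bundle), 1.81e-13 to 1.83e-06 (proliferation), 0.00170 to 0.237 (BMP and TGF-beta, highest without BQ788 replicate 1), 0.000157 to 0.101 (interferon), 9.83e-06 to 0.00572 (unfolded protein response) and 7.30e-06 to 0.00551 (ribosomal proteins). Lists not past the threshold that passed under some of 12 alternatives were fibroblast (5, lowest 0.00291), Schwann cell and neuron (5, lowest 0.0359), adhesion and migration (4, lowest 0.00668), cilium (1, 0.0181) and oxidative phosphorylation (1, 0.00427). Leaving out 1 library, these not past the threshold passed at times: immediate early genes (3 of 6, 0.00680 to 0.979), fibroblast (3, 1.77e-05 to 0.528), adhesion and migration (2, 0.00614 to 0.407), Schwann cell and neuron (2, 0.0354 to 0.0886), mitochondrially encoded proteins (0.00341 without BQ788 replicate 1), hair cell fate (0.0344 without SM control replicate 1) and channels and synapse (0.0370 without BQ788 replicate 3). Except for the tests with more genes or fewer samples, the cause was not tested. Leaving out 1 library reversed the log2 fold change of 6 named genes, none past the threshold: ATOH1 (-0.18 to 0.0187, reversed without BQ788 replicate 3), SOX2 (-0.37 to 0.14, reversed without BQ788 replicate 2 or 3), COL1A2 (-0.54 to 0.13, reversed without BQ788 replicate 2), EDNRA (-0.23 to 0.24), DCN (-0.42 to 0.41) and LUM (-0.39 to 0.61), the last 3 reversed without SM control replicate 3 (-0.06, -0.13 and -0.13) and without BQ788 replicate 1. No named gene past the threshold reversed in any of these settings. Where a library was left out this was fixed in advance, since the groups of these genes did not overlap. Robust eBayes does not enter the camera test, so its list values equal those reported and it was not counted as an alternative for the lists.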

Other observations

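The protein domain groups and all tests in this part were chosen after the data were seen. Of 35 tested genes whose description names a collagen triple helix repeat, 7 fell with BQ788 and none rose. The enrichment adjusted p was 0.00229, and the camera p was 0.000140, and 0.113 with an estimated correlation. Some tested collagen genes, such as COL2A1, COL11A1, COL9A2 and COL6A2, are not among the 35. COL9A1 fell from 34.7 ± 4.92 to 15.4 ± 1.10 FPKM, beside COL9A3, COL22A1 (-1.17), C1QTNF3 (-1.17), LOC101747382 (-1.04), COL17A1 (-0.94) and COL14A1 (-0.67). The fibrillar collagen genes COL1A1 (-0.42), COL1A2 (-0.18) and COL3A1 (-0.79) did not pass over all genes.

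Of 25 tested genes with a core histone domain, which include the Ras exchange factor gene SOS1 (0.17), 21 lay below 0 with BQ788. Their median was -0.24 and 3 passed the threshold, HIST1H2B7L4 (15.5 to 7.22 FPKM), HIST1H2B7 (-0.55) and HIST1H2BO (-0.71). Called genes were not enriched among them (adjusted p = 0.593), while their camera p was 9.88e-05, and 0.0427 with an estimated correlation. Histone genes have many near-identical copies, so the assignment of reads among them is uncertain. Of 20 tested genes with a major facilitator domain, a family of membrane transporters, 4 rose, SLC46A3 (0.70), SLC16A9 (0.41), SLC43A2 (0.35) and SLC37A4 (0.34), with an enrichment adjusted p of 0.00339 (camera p = 0.0120, and p = 0.118 with an estimated correlation).

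The lower collagen genes may reflect fewer cells of the underlying tissue carried over with the epithelium. For mesenchyme this cannot be told apart: the fibroblast list lay 0.88 above the called collagen genes (95% interval -0.06 to 1.81), and its own mean of -0.21 had an interval from -1.11 to 0.68. Cartilage cells cannot be told apart as a cause either. The mean of the tested cartilage markers lay 1.38 above that of the collagen IX genes (1.15 to 1.60). However, collagen IX was compared after its fall was seen, and CHAD (1.03) and EPYC (0.58) raise the marker mean. No tested marker fell as far as any collagen IX gene (lowest MATN3 at -0.41, against COL9A2 at -0.98). COL2A1 was at 57.0 and 46.4 FPKM and CHAD at 38.5 and 80.3 FPKM in controls and with BQ788. Only 5 of 13 markers listed were tested. Another 6 below a mean of 1 FPKM, such as ACAN (0.239 and 0.0957) and HAPLN1 (0.694 and 0.239), were all lower with BQ788. A gene length trend is argued against for the 7 called genes, whose median log2 fold change was -1.11 before its removal and -1.14 after. That 7 of 7 stayed past the threshold adds little, since the removal moved tested genes by a median of only 0.03. A response of the cells to BQ788 stays open as untested.

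Lower hair bundle genes may reflect fewer hair cells. Channel and synapse genes of hair cells lay 0.14 above bundle genes (0.03 to 0.25), but by 0.08 among members with a mean of at least 5 FPKM (0.02 to 0.14), and the interval spanned 0 when members were resampled (-0.04 to 0.31). Channel and synapse genes went both ways, with a mean of -0.11 (-0.34 to 0.13), so fewer hair cells cannot be told apart from a change in bundle genes. Removing the gene length trend left the bundle list at a camera adjusted p of 0.000619, which argues against that trend. A change of bundle genes in response to BQ788 was not tested.

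For the genes with a core histone domain, a length trend may contribute: with it removed the camera p was 0.00286 and the mean log2 fold change went from -0.26 to -0.20, which does not separate it from other causes. Lower capture of RNAs without a poly(A) tail cannot be told apart either. The 89 tested RNAs of biotypes without such a tail had a mean of -0.10 (-0.39 to 0.18). The share of rRNA reads was also lower with BQ788. Genes with the domain, SOS1 among them, were not sorted by whether they carry such a tail. A biological response of histone genes stays open as untested.

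The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 355 genes and the highest of the others 0, and 1 split gave as many. At an unadjusted limma p under 0.05 the real split gave 2690 genes. The split with SM control replicates 1 and 2 and BQ788 replicate 1 on 1 side gave 1965. For the gene lists the real split gave 6 and the others 5 to 10, and 6 of the 10 splits gave as many or more. The number of lists called therefore does not set the real groups apart from other groupings of these libraries. The first principal component held 43.3% of the variance, with SM controls at -15.8, -9.77 and 3.79 and BQ788 libraries at -16.1, 13.1 and 24.8. On the second component, with 32.8%, the controls lay at 5.94, 11.0 and 18.2 and the BQ788 libraries at -21.8, -9.50 and -3.82.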
